A study of Mus musculus with 9 samples.

How the data were processed

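RNA was measured in 9 samples of antigen-specific T cells sorted from mouse spleen 30 days after infection with the Armstrong strain of lymphocytic choriomeningitis virus (LCMV). Per the labels' protocols, RNA was extracted with a column kit for small samples, amplified and tagged with low-input kits that do not mark strand, and sequenced as paired-end reads of 126 bp. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic, STAR, HTSeq, DESeq2 and the mm10 build, without the role of each and without the other versions. The annotation release and the strand setting of the counting were not given in the sources used here.

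The deposited count table holds whole-number counts per gene symbol, not normalized by the authors, with 1 column per sample. A second deposited table of the same samples holds a signal scaled by the authors. Each value was the deposited count times 1 factor per library, and its columns summed to 904417 to 1033517. The scaled table was used only in an alternative test. Of 48663 named entries in the count table, 26449 had a count. A further check of the names found 27 that a spreadsheet had turned into dates, 2 of them duplicated; 20 were tested and together they held 0.243% of the counts, and none of these is discussed by name.

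Samples were grouped by their titles into CD4 control, CD4 ThpokAD and CD8 control, with 3 libraries each. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Total counts per library were 16664474 to 38981516. Low-count genes were removed with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 15738 genes holding at least 99.8% of the counts of every library. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest with trended dispersions) on the deposited counts, with TMM scaling, 1 coefficient per group, all 9 libraries in 1 fit and Benjamini-Hochberg adjustment within each comparison. Genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are edgeR CPM values (counts scaled by TMM library size), as mean ± SD of the 3 libraries. The 3 comparisons share libraries, so they are not independent of one another.

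A fold change against a group with no count was computed against 3 counts summed over that group and is given as a lower bound. For a group with 1 to 3 counts, a ratio with its counting interval is given instead. Such bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

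The test, the libraries in the fit, 32 gene lists, the rule for genes to name and most alternatives were chosen before the data were examined. The lists cover helper lineage, CD8 lineage, cytotoxic and NK receptor, Tfh (follicular helper), Th1, Th2, Th17, Treg (regulatory T cell), central memory and survival, effector and terminal differentiation, inhibitory receptor, apoptosis, T cell transcription factor, cytokine, chemokine receptor and integrin, cell cycle, interferon stimulated, immediate early and heat shock, glycolysis, cholesterol and fatty acid synthesis, fatty acid oxidation, TCR signalling, ribosomal protein and mitochondrially encoded genes, sex-linked genes, and markers of B cells, plasma cells, myeloid cells, dendritic cells with MHC class II, NK cells, erythroid cells, and gamma-delta with NKT cells. Several lists share members. Each list was compared with all other tested genes by camera of limma 3.58.1 on voom log-counts, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The plan named camera on voom-type log-counts and edgeR's camera in the same line, so camera on edgeR's count object was run as an added alternative. Camera with an estimated correlation and fry were run beside it. The list of ribosomal proteins was defined by the form of the symbol and also took in the kinases Rps6ka1, Rps6ka2 and Rps6ka4 and other genes that are not ribosomal proteins.

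The genes to be named were Zbtb7b, Cd4, Cd8a, Cd8b1 and Tnfrsf4 in every comparison. To these were added, per comparison, the 8 genes with the largest log2 fold change in each direction among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, leaving out receptor segments, predicted genes and pseudogenes. Up to 4 called members of each list with the smallest adjusted p were also taken, as were the genes a list is best known for, called or not. Of the genes this rule gave, the text names mostly those that kept their call whichever library was left out.

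Gene coordinates were taken from the GENCODE M21 annotation of the same build, which matched 15215 (96.7%) of the tested symbols, and are 1-based. Since strand was not marked, reads from overlapping genes cannot be told apart: of 163 genes examined, 7 shared over 10% of their exon bases with another annotated gene (Cd7, Cebpb, Foxp3, Ifng, Kif20a, Klrb1c and Rps6ka4). Values of genes with closely similar copies, such as Klra1 and Klra4, Klrc1 and Klrc2, Hspa1a and Hspa1b, and Bcl2a1b and Bcl2a1d, are uncertain in so far as the counting could split reads between copies; shared sequence was not measured here.

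The alternatives were DESeq2 size factors in the same edgeR fit, the Wald test of DESeq2 1.42.0, no low-count filter, a fit of only the 6 libraries compared, the replicate number as a block, robust empirical Bayes, leaving out receptor segments with mitochondrial and ribosomal protein genes, limma-trend on log2 of the scaled signal plus 1, a minimum log2 fold change of 1, and leaving out each library in turn. Bias-adjusted deviances in glmQLFit, thinning of all libraries to equal depth, camera on edgeR's count object and the helper lineage list without Zbtb7b and Tnfrsf4 were added after the data had been seen. The fits were tested on simulated data with known changes in CD4 ThpokAD against CD4 control: of 50 genes changed at each size, 18% were called at 2-fold, 64% at 4-fold, 68% at 8-fold and 76% at 16-fold over the 14738 genes of that fit, with 0 false calls. Camera was tested on the same simulated data. A list of 30 raised genes passed (adjusted p = 1.4e-67) and a list of 29 unchanged genes did not (adjusted p = 0.43). A list of 29 genes with 15 raised and 14 lowered also passed, as higher (adjusted p = 9.69e-05, and 0.00602 with an estimated correlation), so a list call does not by itself show that the members moved one way, and the numbers of members called in each direction are given beside it. Results for 3 single genes are not reported here.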

Results

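Gene expression was measured by RNA sequencing in memory T cells specific for LCMV, sorted from mouse spleen with peptide-MHC tetramers 30 days after an acute infection. CD4 control cells (3 libraries) bound the class II tetramer carrying the viral GP66 peptide and came from mice without Cre. CD4 ThpokAD cells (3 libraries) bound the same tetramer and came from mice in which Ox40-Cre acts on floxed alleles of Thpok. CD8 control cells (3 libraries) bound the class I tetramer carrying the GP33 peptide and came from mice without Cre. Thpok, the product of Zbtb7b, is the transcription factor that directs T cells to the CD4 helper lineage and restrains cytotoxic genes. Ox40, the product of Tnfrsf4, is a costimulatory receptor of activated CD4 T cells.

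The CD4 control libraries held 16664474, 18357021 and 17393853 counts. The CD4 ThpokAD libraries held 20245185, 18517118 and 19256630, and the CD8 control libraries 22796339, 19850495 and 38981516. Replicates differed by far more than counting noise, with chi-square values per degree of freedom of 34.7 to 167. The Pearson correlation of their log2 CPM across genes, which are not independent replicates, was 0.948 to 0.964. The first principal component, with 28.95% of the variance, separated CD8 control from both CD4 groups. The next, with 18.02%, separated CD4 ThpokAD from CD4 control with CD8 control between them.

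The targeted gene was examined first. Zbtb7b (chromosome 3, 89377644 to 89394776, minus strand) stood at 44.97 ± 5.68 CPM in CD4 control, 0.807 ± 0.0953 CPM in CD4 ThpokAD and 20.8 ± 2.87 CPM in CD8 control (mean ± SD, n = 3). The ThpokAD libraries lay between 0.698 and 0.875 CPM and the CD4 control libraries between 38.5 and 48.9 CPM, so that the level went with the label in every library. The log2 fold change of CD4 ThpokAD against CD4 control was -5.79 (SE 0.264, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.35e-05). Gene-level counts do not tell which exons the remaining reads came from. Tnfrsf4, the gene whose locus drives Cre, was 4.66-fold lower in CD4 ThpokAD than in CD4 control (81.1 ± 24.2 against 378 ± 53.3 CPM, adjusted p = 0.0201). That call was lost without any 1 of the CD4 control libraries or without ThpokAD replicate 1 or 3 (adjusted p = 0.0595 to 0.0928).

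The comparison of CD4 ThpokAD with CD4 control asked how CD4 memory cells that lost Thpok after activation differed from control cells. Only the ThpokAD mice carried Cre, so effects of Cre or of its locus and of the loss of Thpok cannot be told apart. ThpokAD cells carried high levels of transcripts of the cytotoxic machinery and of chemokines. Granzyme A (Gzma) was at 1169 ± 216 CPM against 5.105 ± 2.77 CPM, granzyme B (Gzmb) at 721 ± 88.2 against 45.2 ± 9.43, and perforin (Prf1) at 522 ± 34.8 against 53.2 ± 17.3. The chemokines Ccl4 and Ccl5 were at 1272 ± 273 against 52.9 ± 23.6 and 12390 ± 1490 against 1746 ± 158. The fractalkine receptor Cx3cr1 and the inhibitory lectin receptor Klrg1, both carried by terminal effector cells, rose 47.9-fold and 25.8-fold. The cells in turn held less of the IL-7 receptor chain Il7r (315 ± 42.3 against 1108 ± 176 CPM), of the memory and follicular factor Tcf7 (650 ± 33.6 against 1502 ± 113) and of the costimulatory receptor Icos (825 ± 103 against 1896 ± 304). All of these passed the edgeR test, with adjusted p between 3.35e-05 and 0.00624, and kept their calls whichever library was left out.

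**Figure D1:**
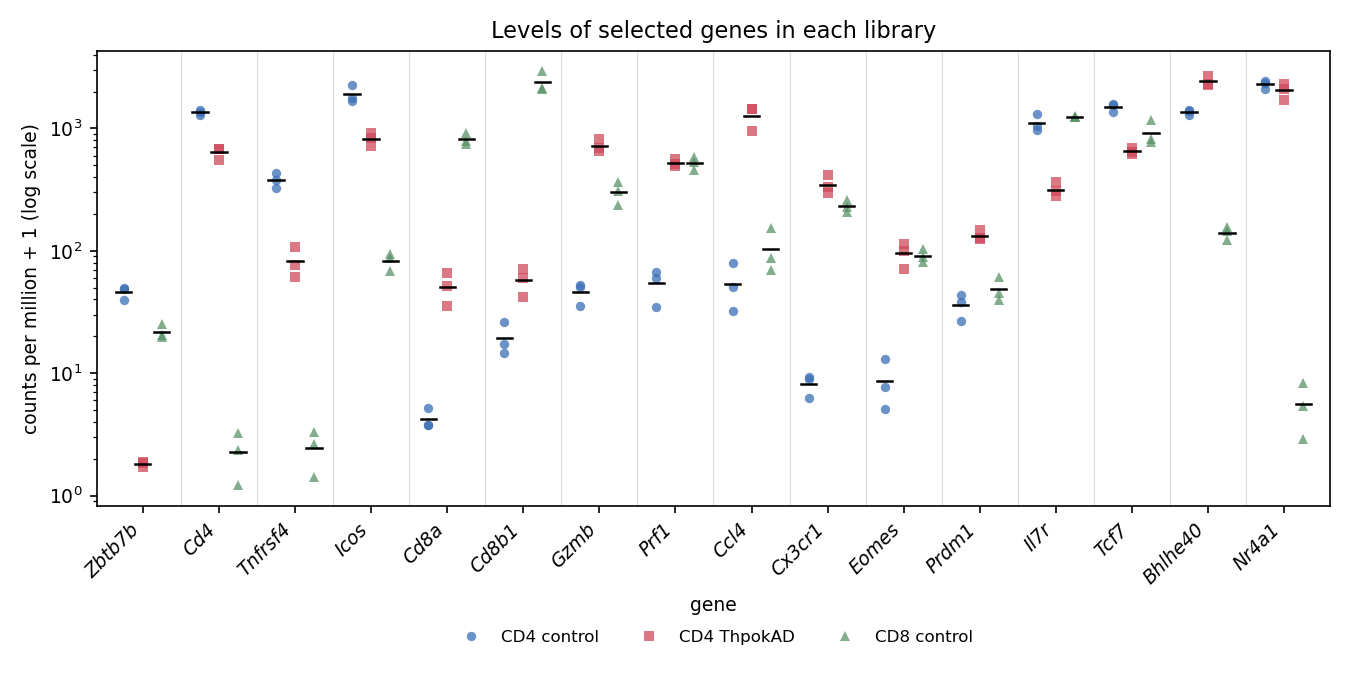
CPM plus 1, on a log scale, of 16 genes in each of the 9 libraries (points) with group means (bars). Zbtb7b was at 0.807 CPM in CD4 ThpokAD, while Gzmb, Prf1, Ccl4 and Cx3cr1 were higher there than in CD4 control and Il7r and Tcf7 lower.

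In all, 285 genes rose and 146 fell in CD4 ThpokAD, 2.74% of the 15738 tested. Of these, 225 and 84 changed at least 2-fold. Genes with the largest rises included some without a count in CD4 control. The metalloprotease gene Adamts14 (chromosome 10, 61197112 to 61273438) was at least 393-fold higher at 23.2 ± 7.86 CPM. The receptor tyrosine kinase gene Ret was at least 320-fold, Tmem151a at least 225-fold and Plekha6 at least 223-fold higher. Kcnj8, a subunit of ATP-sensitive potassium channels, rose 72.8-fold from 1.26 ± 1.44 CPM. Genes that fell included Ramp3, which helps calcitonin-type receptors to the cell surface (9.39-fold lower), Espn, an actin-bundling protein (8.66-fold lower), and the pseudokinase Trib2 (5.41-fold lower). Leaving out 1 CD4 library changed the counts. Without CD4 control replicates 1, 2 and 3 in turn, 150, 140 and 166 genes rose and 54, 53 and 60 fell. Without ThpokAD replicates 1, 2 and 3 in turn, 131, 171 and 154 rose and 50, 103 and 63 fell. Of 71 called genes that the rule named, 41 kept their call whichever library was left out.

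The lists of CD8 and effector genes rose in CD4 ThpokAD. Of the 9 tested members of the CD8 lineage list, 8 rose and none fell (9 rose when adjusted over the list alone; camera adjusted p = 5.71e-14, and 0.0061 with an estimated correlation). Among them were the T-box factor Eomes (94.0 ± 21.8 against 7.60 ± 3.98 CPM), the receptors Cd160 (18.8-fold) and Klrk1 (5.97-fold), and Cd8a itself. The rise of the co-receptor genes left them low, with Cd8a at 49.6 ± 15.2 CPM and Cd8b1 at 56.4 ± 14.8 CPM. Their levels were 814 ± 88.3 and 2379 ± 469 CPM in CD8 control and 3.245 ± 0.824 and 18.3 ± 6.08 CPM in CD4 control. The call of Cd8b1 (adjusted p = 0.0178) was lost without CD4 control replicate 1 or 3 or ThpokAD replicate 1 or 3 (adjusted p = 0.0627 to 0.0842). Runx3, a factor of the CD8 lineage, was at 315 ± 26.1 against 197 ± 17.7 CPM and was not called (adjusted p = 0.127). It was called without CD8 control replicate 3 (adjusted p = 0.0225), when only the 6 libraries compared were fitted (0.0278) and by DESeq2's Wald test (0.031).

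Of 30 tested members of the cytotoxic and NK receptor list, 22 rose and none fell (24 and 2 when adjusted over the list alone; median log2 fold change 2.55, and 2.54 with genes without counts at their bounds; camera adjusted p = 8.08e-30, and 0.0123 with an estimated correlation). The effector and terminal differentiation list had 18 of 25 members higher and none lower (21 higher when adjusted over the list alone; median 1.60; adjusted p = 1.28e-27, and 0.0123 with an estimated correlation). It includes Cx3cr1, Klrg1 and the repressor Prdm1, which encodes Blimp1 (132 ± 12.5 against 35.2 ± 8.87 CPM). In the Th1 list, 11 of 21 members rose and 2 fell (13 and 4 over the list alone; adjusted p = 5.85e-09, and 0.0153 with an estimated correlation). Among those that rose were the chemokine receptor Cxcr6 (2.62-fold), the transcriptional inhibitor Id2 (2.42-fold) and the granule protein Nkg7 (3.51-fold). The 2 that fell were the chemokine receptor Cxcr3 and Ly6c1. The Th1 factor Tbx21 rose 2.08-fold, a call lost without CD4 control replicate 1 or 3 or ThpokAD replicate 3 (adjusted p = 0.0574 to 0.0635). Its product's classical target Ifng was at 438 ± 92.0 against 216 ± 49.1 CPM and was not called (adjusted p = 0.117, and 0.00832 by DESeq2's Wald test, which called it). The chemokine receptor and integrin list had 11 of 34 members higher and 3 lower (13 and 6 over the list alone; adjusted p = 9.85e-06, lost at adjusted p = 0.0856 with an estimated correlation). The integrin gene Itgax rose 13.4-fold. The list of NK cell markers, with 4 of 12 members higher and none lower (4 higher over the list alone), also passed (adjusted p = 4.97e-06, and 0.0123 with an estimated correlation). The NK markers Klrb1c, at 69.1 ± 22.7 against 11.5 ± 5.47 CPM, Klra4, at least 40.8-fold higher, and Gzma were among those that rose. The activating receptor Ncr1 had no count in CD4 control and stood at 1.79 ± 1.63 CPM in ThpokAD.

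Genes of the helper program fell. Of the 11 helper lineage genes, 6 fell and none rose (8 fell over the list alone; median log2 fold change -1.20; camera adjusted p = 7.57e-14, and 0.0123 with an estimated correlation). The list includes the deleted Zbtb7b and Tnfrsf4, the Cre locus. Without both, 4 of 9 fell (6 over the list alone; median -1.09; adjusted p = 8.12e-10, and 0.0123 with an estimated correlation). Tnfsf11, which encodes RANKL, was at 22.2 ± 4.23 against 108 ± 1.54 CPM, and Icos was 2.30-fold lower. Cd4 itself was at 635 ± 72.4 CPM in CD4 ThpokAD and 1354 ± 57.2 CPM in CD4 control, without overlap between the libraries. Its log2 fold change of -1.09 (SE 0.416) was not called (adjusted p = 0.241). It was called when only the 6 libraries compared were fitted (adjusted p = 0.00482), with bias-adjusted deviances (adjusted p = 0.00406) and without CD8 control replicate 3 (adjusted p = 0.00997). Over the other settings the adjusted p was 0.0601 to 0.459. The Tfh list had 5 of 23 members lower and none higher (10 lower and 1 higher over the list alone; adjusted p = 2.67e-09, lost at adjusted p = 0.15 with an estimated correlation). Angptl2 was 5.035-fold and Tcf7 2.31-fold lower. The follicular regulator Bcl6 was at 66.3 ± 24.0 against 104 ± 29.8 CPM (adjusted p = 0.354). The follicle-homing receptor Cxcr5, at 73.5 ± 60.4 against 228 ± 43.7 CPM, was called only without ThpokAD replicate 2 among the fits that left out 1 library (adjusted p = 0.165, and 0.0196 without it), and also by DESeq2's Wald test (0.0164).

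The central memory and survival list fell as well, with 8 of 21 members lower and none higher (10 lower and 2 higher over the list alone; adjusted p = 1.26e-08, and 0.0123 with an estimated correlation). Il7r fell by 1.81 on the log2 scale, the genome organiser Satb1 by 1.17 and the neuronal vesicle protein Nsg2 by 1.94. The survival gene Bcl2 was 2.165-fold lower, a call lost without CD4 control replicate 1 or 2, ThpokAD replicate 1 or 3, or CD8 control replicate 1 or 2 (adjusted p = 0.0506 to 0.127). The lymph node homing receptor Ccr7 was at 192 ± 55.7 against 401 ± 60.4 CPM and was not called (adjusted p = 0.0916), but was by DESeq2's Wald test (0.0036) and limma-trend (0.0436).

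Cell cycle genes were higher in CD4 ThpokAD: 10 of 34 list members rose and none fell (29 rose over the list alone; median log2 fold change 2.45; camera adjusted p = 1.28e-27, and 0.0225 with an estimated correlation). Stmn1, a microtubule regulator, was at 51.9 ± 7.75 against 6.21 ± 1.02 CPM, and the replication licensing factor Mcm5 at 163 ± 22.8 against 41.5 ± 8.04 CPM.

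The remaining 6 lists that passed camera in CD4 ThpokAD lost their calls with an estimated correlation. The Treg list was higher (3 of 16 members rose and 1 fell, 6 and 2 over the list alone; adjusted p = 0.0417, and adjusted p = 0.414 with an estimated correlation). Its member Lrrc32, which anchors latent TGF-beta at the cell surface, was at 40.1 ± 2.00 against 2.78 ± 1.34 CPM. Foxp3, the factor of regulatory T cells, was at 29.2 ± 19.4 against 2.28 ± 2.26 CPM and was not called (adjusted p = 0.207), with 50.1, 11.8 and 25.6 CPM in the ThpokAD libraries. It was called by DESeq2's Wald test (adjusted p = 0.0449), limma-trend (0.0194) and with bias-adjusted deviances (0.0263). The Treg call was lost without CD4 control replicate 2 (adjusted p = 0.0504), ThpokAD replicate 1 (0.147) or CD8 control replicate 3 (0.0519). It was also lost when only the 6 libraries compared were fitted (0.12) and in directional fry (0.14). The myeloid markers were higher (1 of 22 rose, 1 over the list alone; adjusted p = 0.0288, and adjusted p = 0.476 with an estimated correlation). That call was lost without CD4 control replicate 1 (0.0958) or 2 (0.0504) or ThpokAD replicate 2 (0.138). The TCR signalling list was lower (2 of 32 members fell, 3 over the list alone; adjusted p = 0.00261, and adjusted p = 0.2 with an estimated correlation). Ribosomal protein genes were lower too (median log2 fold change -0.365, 1 of 96 called higher and 0 over the list alone; adjusted p = 1.55e-07, and adjusted p = 0.499 with an estimated correlation). The called member was the kinase gene Rps6ka4, whose call was lost without any 1 library except CD8 control replicate 2 (adjusted p = 0.0535 to 0.178). So were mitochondrially encoded genes (median -0.49, 0 of 20 called and 0 over the list alone; adjusted p = 0.00127, and adjusted p = 0.499 with an estimated correlation). Immediate early and heat shock genes were slightly lower (median -0.19, 1 of 29 rose and 1 fell, 1 and 2 over the list alone; adjusted p = 0.0133, and adjusted p = 0.414 with an estimated correlation), and lost their call without CD4 control replicate 2 (0.101) or ThpokAD replicate 1 (0.113).

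The other 16 lists did not pass camera in CD4 ThpokAD against CD4 control. The adjusted p was 0.529 for the Th2 list, 0.406 for Th17, 0.124 for inhibitory receptors, 0.624 for apoptosis, 0.406 for T cell transcription factors, 0.774 for cytokines and 0.723 for interferon stimulated genes. It was 0.554 for glycolysis, 0.296 for cholesterol and fatty acid synthesis, 0.144 for fatty acid oxidation and 0.0757 for sex-linked genes. Among markers of other cells it was 0.23 for B cells, 0.194 for plasma cells, 0.231 for dendritic cells with MHC class II, 0.838 for erythroid cells and 0.332 for gamma-delta and NKT cells. The inhibitory receptor and dendritic cell lists passed without ThpokAD replicate 3 (adjusted p = 0.00437 and 0.0121), and the sex-linked list without CD4 control replicate 3 (0.0228). The sex-linked list also passed camera as lower with the replicate number as a block (0.0416). The gamma-delta and NKT list passed as higher without the low-count filter (0.0131). Median, mean and test differed in sign for the Th2, apoptosis, interferon stimulated and erythroid lists. Members of some of these lists changed in both directions. Of 39 transcription factors, 7 rose and 4 fell (11 and 6 over the list alone). Ikzf3, a relative of the lymphoid factor Ikaros, was 2.49-fold higher. Of 21 cytokine genes, 4 rose and 3 fell (8 and 7 over the list alone).

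The comparison of CD8 control with CD4 control measured how far the virus-specific memory cells of both lineages differed. Lineage, viral peptide, tetramer class and sort go together in these groups, so their effects cannot be told apart. CD8 control cells held more of the co-receptor genes Cd8a (814 ± 88.3 against 3.245 ± 0.824 CPM) and Cd8b1 (2379 ± 469 against 18.3 ± 6.08). They also held more of the granule genes Gzma (455 ± 195 against 5.105 ± 2.77), Gzmb (301 ± 62.9 against 45.2 ± 9.43) and Prf1 (522 ± 64.4 against 53.2 ± 17.3) and of the lymphocyte egress receptor S1pr5 (306 ± 65.5 against 3.053 ± 2.165). CD4 control cells held more Cd4 (1354 ± 57.2 against 1.28 ± 1.02 CPM), Tnfrsf4 (378 ± 53.3 against 1.44 ± 0.943) and Icos (1896 ± 304 against 81.6 ± 13.0). The orphan nuclear receptor genes Nr4a1 and Nr4a2, switched on by TCR signals, were at 2303 ± 166 and 727 ± 85.6 CPM in CD4 control and at 4.57 ± 2.72 and 2.37 ± 0.676 CPM in CD8 control. These 11 genes passed the edgeR test with adjusted p between 1.9e-06 and 0.000197, in every fit that left out 1 library.

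In all, 808 genes were higher and 1031 lower in CD8 control, 11.7% of those tested, of which 513 and 750 changed at least 2-fold. Without a count in CD4 control were Adamts14, Pald1, Ret and Plekha6, at least 257-fold, 281-fold, 295-fold and 208-fold higher in CD8 control. Without a count in CD8 control were Ramp3, Tnfsf11, the thymocyte factor gene Tox2 and the angiopoietin-like gene Angptl2, at least 6110-fold, 3060-fold, 2060-fold and 1850-fold lower. Zbtb7b was 2.167-fold lower in CD8 control (log2 fold change -1.12, SE 0.21, adjusted p = 0.00972). The call was lost without CD4 control replicate 2 (adjusted p = 0.0516) or 3 (0.0515). The count of higher genes was 442, 421 and 527 without CD4 control replicates 1, 2 and 3 and 492 without CD8 control replicate 3. That of lower genes was 637 without CD4 control replicate 2. Of 103 called genes that the rule named, 86 kept their call whichever library was left out.

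Lists of helper functions were lower in CD8 control. All but 1 of the 11 helper lineage genes fell (10, also 10 over the list alone; median log2 fold change -3.795; adjusted p = 1.6e-13, and 0.0222 with an estimated correlation). Of 23 Tfh genes, 18 fell (21 over the list alone; adjusted p = 5.6e-15, and adjusted p = 0.078 with an estimated correlation). Among them were Bcl6 (5.96-fold), Cxcr5 (11.6-fold), the inhibitory receptor gene Pdcd1 (10.2-fold) and Il21, without a count in CD8 control and at least 963-fold lower. The Th2 list had 3 of 7 members lower (5 over the list alone; median -5.81, and -5.41 with genes without counts at their bounds; adjusted p = 0.00142, and adjusted p = 0.0895 with an estimated correlation). The Th17 list had 3 of 6 lower (4 over the list alone; adjusted p = 0.00161, and adjusted p = 0.078 with an estimated correlation). Of 16 Treg genes, 9 were lower (11 over the list alone; adjusted p = 3.41e-06, and adjusted p = 0.078 with an estimated correlation). These included the checkpoint receptor Ctla4 (7.96 ± 1.49 against 263 ± 4.598 CPM). Inhibitory receptors had 9 of 14 members lower and 1 higher (9 and 2 over the list alone; adjusted p = 1.92e-05, and adjusted p = 0.0901 with an estimated correlation). Cytokine genes had 8 of 21 lower and 1 higher (12 and 4 over the list alone; adjusted p = 0.0131, and adjusted p = 0.0972 with an estimated correlation).

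The immediate early and heat shock list was lower in CD8 control, with 22 of 29 members down and 1 up (23 and 1 over the list alone; median -2.44; adjusted p = 1.15e-20, and 0.0249 with an estimated correlation). The stress factor gene Atf3 was at 77.7 ± 10.1 CPM in CD4 control and at 0.0164 ± 0.0285 CPM in CD8 control. The ratio was 0.000301 with a 95% counting interval of 3.65e-05 to 0.00109. Fosl2, an AP-1 subunit, was 10.2-fold and the activation marker Cd69 12.4-fold lower. T cell transcription factors had 17 of 39 members lower and 6 higher (20 and 8 over the list alone; adjusted p = 0.000382, and adjusted p = 0.0782 with an estimated correlation). Bhlhe40 was 9.76-fold and Nfil3 6.03-fold lower. Central memory and survival genes had 8 of 21 lower and 1 higher (11 and 3 over the list alone; adjusted p = 0.00161, and adjusted p = 0.078 with an estimated correlation). Ccr7 was 7.15-fold lower, while Il7r was at 1243 ± 17.1 against 1108 ± 176 CPM (adjusted p = 0.501). Apoptosis genes had 9 of 26 lower (11 lower and 4 higher over the list alone; adjusted p = 0.00246, and adjusted p = 0.078 with an estimated correlation). TCR signalling genes had 8 of 32 lower and 1 higher (11 and 3 over the list alone; adjusted p = 0.00258, and adjusted p = 0.125 with an estimated correlation).

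The CD8 lineage list was higher in CD8 control (7 of 9, also 7 over the list alone; adjusted p = 5.09e-11, and 0.0121 with an estimated correlation), with Eomes at 89.6 ± 11.6 against 7.60 ± 3.98 CPM. The Th1 list was higher too (10 of 21 higher and 2 lower, 13 and 3 over the list alone; adjusted p = 4.69e-07, and 0.0471 with an estimated correlation). Tbx21 was 1.915-fold and Id2 4.35-fold higher. Cytotoxic and NK receptor genes had 17 of 30 higher and 5 lower (20 and 5 over the list alone; adjusted p = 2.3e-07, and adjusted p = 0.0972 with an estimated correlation). Effector and terminal differentiation genes had 17 of 25 higher and 3 lower (18 and 3 over the list alone; adjusted p = 2.13e-09, and adjusted p = 0.078 with an estimated correlation). Cx3cr1 was 32.0-fold and Klrg1 22.15-fold higher. The NK cell markers had 5 of 12 higher and 1 lower (5 and 1 over the list alone; adjusted p = 0.0268, and adjusted p = 0.0972 with an estimated correlation). Klrb1c was 10.6-fold higher. Runx3, at 265 ± 73.2 against 197 ± 17.7 CPM, was called only without CD8 control replicate 3 among these fits (adjusted p = 0.21, and 0.0183 without it). Prdm1 was at 47.7 ± 11.4 against 35.2 ± 8.87 CPM (adjusted p = 0.279).

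Among the other lists, MHC class II and dendritic cell markers were lower in CD8 control (4 of 14 lower and 1 higher, 4 and 1 over the list alone; adjusted p = 0.024, and adjusted p = 0.258 with an estimated correlation). The invariant chain gene Cd74 was at 164 ± 47.5 against 582 ± 161 CPM. The call of that list was lost without CD8 control replicate 3 (adjusted p = 0.127). Myeloid markers were lower (3 of 22, 5 over the list alone; adjusted p = 0.00445, and adjusted p = 0.258 with an estimated correlation). Plasma cell markers were lower (1 of 5, 1 over the list alone; adjusted p = 0.0256, and adjusted p = 0.0972 with an estimated correlation), with the secretory factor gene Xbp1 (136 ± 10.9 against 360 ± 4.93 CPM) as the called member. Not all plasma cell markers went that way. Jchain was on average higher in CD8 control, at 129 ± 145 against 30.9 ± 26.7 CPM, and was not called. Its level varied by library, with 0, 286 and 102 CPM in CD8 control replicates 1, 2 and 3. The plasma cell call was lost without CD4 control replicate 1 (0.0726), 2 (0.0781) or 3 (0.12), ThpokAD replicate 1 (0.0988), 2 (0.0846) or 3 (0.0964), or CD8 control replicate 1 (0.351). Cholesterol and fatty acid synthesis genes had 5 of 26 lower (5 over the list alone; adjusted p = 0.00973, and adjusted p = 0.0972 with an estimated correlation). Ribosomal protein genes (3 of 96 higher and 1 lower, 0 over the list alone; median -0.29; adjusted p = 0.000597, and adjusted p = 0.553 with an estimated correlation) lost their call without CD8 control replicate 3 (0.662). Mitochondrially encoded genes (2 of 20 lower, 2 over the list alone; adjusted p = 0.000129) lost theirs at adjusted p = 0.324 with an estimated correlation. CD8 control replicate 3 stood apart in these classes, with 1.08% of its counts mitochondrial and 1.195% ribosomal, against 2.44% and 2.57% and 2.41% and 2.41% in replicates 1 and 2. It also held more counts in all (38981516 against 22796339 and 19850495). The 9 lists that did not pass were chemokine receptors and integrins (adjusted p = 0.281), cell cycle (0.567), interferon stimulated (0.287), glycolysis (0.23), fatty acid oxidation (0.123), B cells (0.477), erythroid cells (0.665), gamma-delta and NKT cells (0.884) and sex-linked genes (0.123). Median, mean and test differed in sign for the chemokine receptor, interferon stimulated and gamma-delta lists. A list that did not pass could still hold changes in both directions. Of 34 chemokine receptor and integrin genes, 13 were higher and 8 lower in CD8 control (13 and 11 over the list alone). That list passed fry in either direction (adjusted p = 1.04e-07). Of 32 interferon stimulated genes, 4 were higher and 4 lower (8 and 4 over the list alone).

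**Figure D2:**
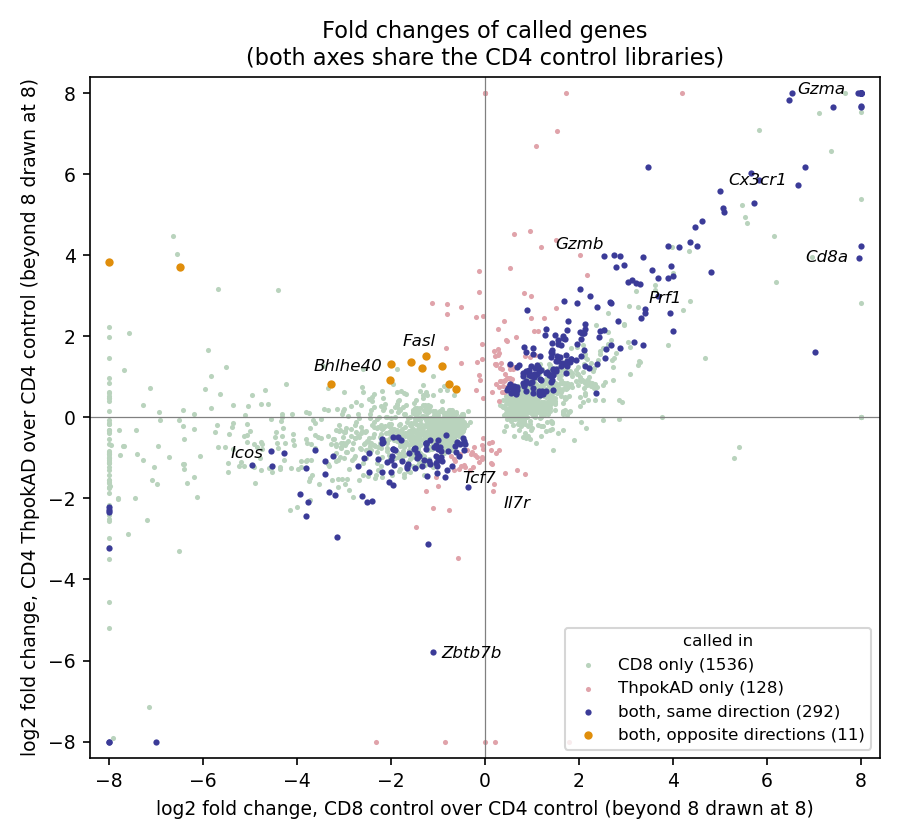
Log2 fold changes of CD4 ThpokAD against CD4 control (vertical axis) and CD8 control against CD4 control (horizontal axis) for genes called in at least 1 of these comparisons, with values beyond 8 drawn at 8 and colours for where each gene was called. Both axes share the 3 CD4 control libraries; 194 genes were called higher and 98 lower in both.

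The comparison of CD4 ThpokAD with CD8 control asked what still separated Thpok-deficient CD4 cells from CD8 memory cells. Here too lineage, viral peptide, tetramer class and sort go together, and genotype with them. ThpokAD cells held more of 9 of the 11 helper lineage genes, Cd4 among them. Cd4 was at 635 ± 72.4 against 1.28 ± 1.02 CPM, Icos at 825 ± 103 against 81.6 ± 13.0 and Tnfrsf4 at 81.1 ± 24.2 against 1.44 ± 0.943. They held 16.4-fold less Cd8a and 42.1-fold less Cd8b1, and 25.6-fold less Zbtb7b. Levels of Prf1 (522 ± 34.8 against 522 ± 64.4 CPM, adjusted p = 0.998), Eomes (94.0 ± 21.8 against 89.6 ± 11.6, adjusted p = 0.948) and Tbx21 (607 ± 79.6 against 559 ± 95.6, adjusted p = 0.77) were not separable. Gzmb was 2.39-fold and Ccl4 12.4-fold higher in ThpokAD (adjusted p = 0.00753 and 0.00125).

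In all, 729 genes were higher and 301 lower in CD4 ThpokAD than in CD8 control, 6.545% of those tested, of which 573 and 174 changed at least 2-fold. Genes without a count in CD8 control included Lrrc32, Tox2, Ramp3 and Tnfsf11, at least 1140-fold, 1030-fold, 650-fold and 629-fold higher in ThpokAD. Higher genes numbered 446 and 438 without ThpokAD replicates 1 and 2. Lower genes numbered 143, 180 and 173 without ThpokAD replicates 1, 2 and 3 and 166, 155 and 187 without CD8 control replicates 1, 2 and 3. Of 93 called genes that the rule named, 70 kept their call whichever library was left out.

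The helper lineage list was higher in ThpokAD (9 of 11 higher and 1 lower, 9 and 1 over the list alone; adjusted p = 4.35e-09, and 0.0356 with an estimated correlation). So were the Th2 (4 of 7, 5 over the list alone; adjusted p = 0.000929, and 0.0398 with an estimated correlation) and Th17 lists (3 of 6, 6 over the list alone; adjusted p = 0.000121, and 0.0398 with an estimated correlation). The Treg list was higher (10 of 16, 11 over the list alone; adjusted p = 1.84e-11, and 0.0356 with an estimated correlation). The retinoid-related receptor gene Rora was 3.14-fold and Ctla4 40.35-fold higher. Tfh genes had 11 of 23 higher (16 higher and 1 lower over the list alone; adjusted p = 1.33e-08, and adjusted p = 0.13 with an estimated correlation), Bcl6 being 3.80-fold higher. Inhibitory receptors had 9 of 14 higher (11 over the list alone; adjusted p = 3.54e-12, and 0.037 with an estimated correlation). Pdcd1 was at 416 ± 125 against 24.9 ± 5.30 CPM and Tigit at 109 ± 31.7 against 9.76 ± 1.00 CPM. Cytokine genes had 11 of 21 higher and 1 lower (15 and 1 over the list alone; adjusted p = 1.94e-07, and 0.0356 with an estimated correlation). Ifng was 4.39-fold higher and Ltb, which encodes lymphotoxin beta, 2.13-fold lower.

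Immediate early and heat shock genes were higher in ThpokAD, with 21 of 29 members up (22 up and 1 down over the list alone; median 2.58; adjusted p = 9.94e-24, and 0.0356 with an estimated correlation). Nr4a1 was at 2040 ± 320 against 4.57 ± 2.72 CPM. Cell cycle genes had 14 of 34 higher (28 over the list alone; median 3.07; adjusted p = 4.07e-20, and 0.0398 with an estimated correlation). Ccnb1 was 10.3-fold and Kif20a 15.55-fold higher. T cell transcription factors had 13 of 39 higher and 4 lower (17 and 5 over the list alone; adjusted p = 2.73e-06, and 0.0398 with an estimated correlation). Bhlhe40 was at 2420 ± 216 against 140 ± 17.0 CPM, and Id2 was 1.80-fold lower. Apoptosis genes had 10 of 26 higher and 1 lower (11 and 2 over the list alone; adjusted p = 0.00109, and 0.0398 with an estimated correlation). Fasl was 7.58-fold higher and Bcl2 2.38-fold lower.

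The CD8 lineage list was lower in ThpokAD (4 of 9 lower and 1 higher, 5 and 1 over the list alone; adjusted p = 0.00275, and 0.0462 with an estimated correlation), with Klrk1 2.57-fold lower. Cytotoxic and NK receptor genes were higher (9 of 30 higher and 2 lower, 13 and 4 over the list alone; adjusted p = 0.000921, and adjusted p = 0.251 with an estimated correlation). Effector and terminal differentiation genes were higher (6 of 25 higher and 1 lower, 9 and 1 over the list alone; adjusted p = 0.000727, and adjusted p = 0.159 with an estimated correlation). Chemokine receptors and integrins were higher (7 of 34 higher and 1 lower, 12 and 2 over the list alone; adjusted p = 0.00312, and adjusted p = 0.152 with an estimated correlation). Cholesterol and fatty acid synthesis genes were higher (2 of 26, 3 over the list alone; adjusted p = 0.0287, and adjusted p = 0.159 with an estimated correlation), whose call was lost without ThpokAD replicate 1 (0.143). Myeloid markers were higher (7 of 22, 13 over the list alone; adjusted p = 8.26e-07, and adjusted p = 0.0734 with an estimated correlation). MHC class II and dendritic cell markers were higher (4 of 14, 5 over the list alone; adjusted p = 0.00138, and adjusted p = 0.152 with an estimated correlation). The adhesion molecule gene Vcam1 was 5.06-fold and Cd74 4.76-fold higher. Foxp3, at 29.2 ± 19.4 against 0.0918 ± 0.138 CPM, was called (adjusted p = 0.0226) but not without ThpokAD replicate 1 or 3 or CD8 control replicate 2 or 3 (adjusted p = 0.0505 to 0.0869).

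The 14 lists that did not pass in this comparison were Th1 (adjusted p = 0.209), central memory and survival (0.607), interferon stimulated (0.209), glycolysis (0.427), fatty acid oxidation (0.667), TCR signalling (0.284), B cells (0.726), plasma cells (0.0916), NK cells (0.427), erythroid cells (0.607), gamma-delta and NKT cells (0.379), sex-linked (0.715), ribosomal protein (0.427) and mitochondrially encoded genes (0.115). Ribosomal protein genes passed as lower without CD8 control replicate 3 (adjusted p = 2.28e-11), and mitochondrially encoded genes as higher without CD8 control replicate 1 (0.0118) or 2 (0.00724). Within the memory list Il7r was 3.945-fold lower and Ccr7 3.43-fold higher in ThpokAD, and Tcf7 was at 650 ± 33.6 against 918 ± 214 CPM (adjusted p = 0.0985). Median, mean and test differed in sign for the Th1, central memory, interferon stimulated and fatty acid oxidation lists. Some of these lists changed in both directions. Of 21 Th1 genes, 3 were higher and 4 lower in ThpokAD (5 and 5 over the list alone). Of 21 central memory and survival genes, 4 were higher and 4 lower (5 and 8 over the list alone). Of 32 TCR signalling genes, 4 were higher and 2 lower (7 and 5 over the list alone).

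**Figure D3:**
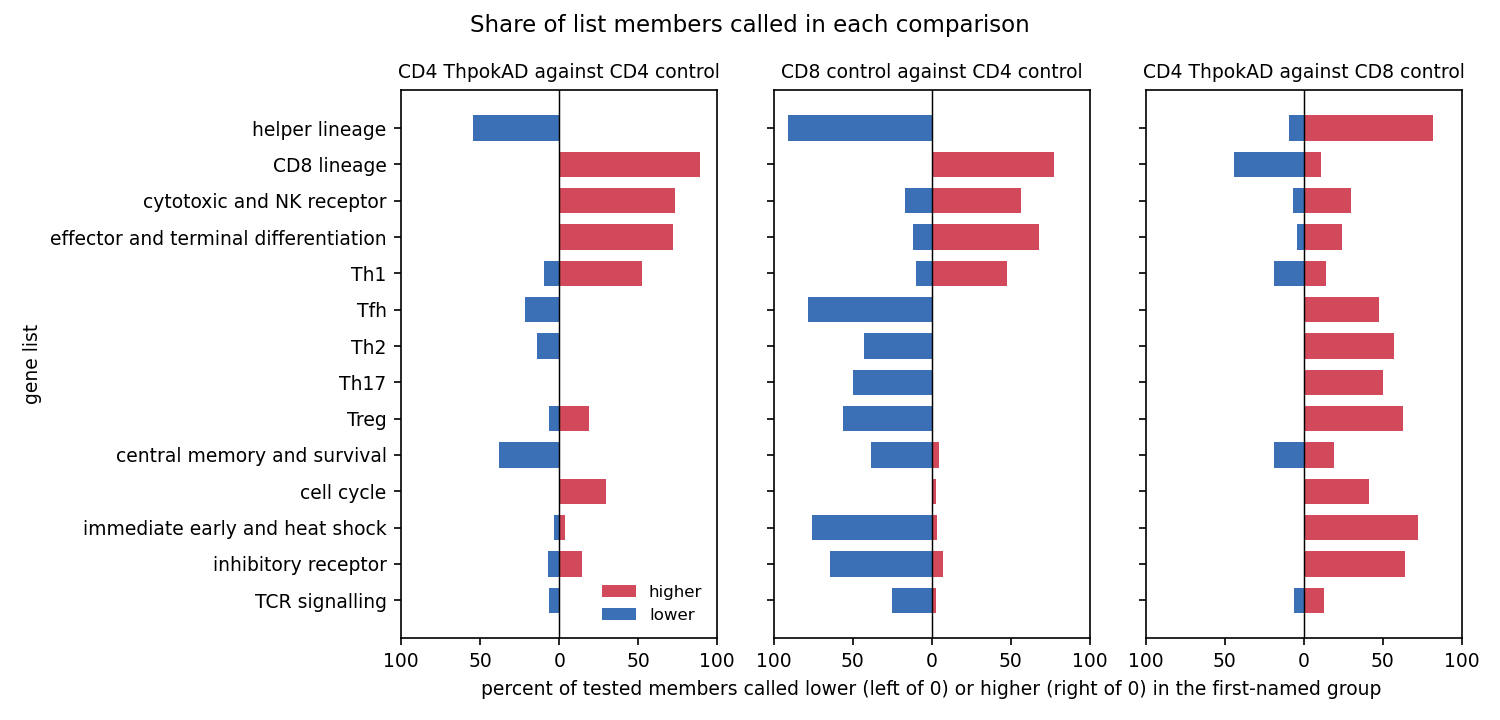
Percent of the tested members of 14 gene lists called lower (left of 0) or higher (right of 0) in the first-named group, in each of the 3 comparisons. In CD4 ThpokAD against CD4 control, 22 of 30 cytotoxic and NK receptor genes were higher, and in CD8 control against CD4 control 22 of 29 immediate early and heat shock genes were lower.

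Genes called in CD4 ThpokAD were set beside those called in CD8 control, each against the same 3 CD4 control libraries. Higher in both were 194 genes, where 14.63 would be shared by independent calls. Lower in both were 98 (9.56 by independent calls). Higher in ThpokAD and lower in CD8 control were 11 genes (18.67), and lower in ThpokAD and higher in CD8 control 0 (7.5, by edgeR). Over all 15738 genes the covariance of the fold changes was 0.712, against a mean of 0.296 in 30 simulations of unchanged groups with the same shared controls. Their correlation was 0.474 against 0.505 in the simulations. Unchanged groups that share controls already give about this simulated value, and changes in only 1 comparison lower it, so the correlation does not decide. The 30 simulations gave 0 shared calls in every direction, but they hold no changed genes. Part of the shared calls may come from the shared controls, since 3 libraries cannot be divided into separate control sets.

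Of the 194 genes higher in both, 166 were not separable between ThpokAD and CD8 control, 21 were lower in ThpokAD, among them Cd8a, Id2 and Klrk1. Another 7 were higher in ThpokAD, among them Gzmb and Lgals3. Of the 98 lower in both, 48 were not separable from CD8 control, 47 were still higher than in CD8 control, among them Icos and Tnfsf11. Below CD8 control were 3, Zbtb7b, Espn and the membrane protein gene Sidt1, the last chosen after its values were seen. Among the 11 that went opposite ways were Bhlhe40 (2420 ± 216 CPM in ThpokAD, 1365 ± 64.9 in CD4 control and 140 ± 17.0 in CD8 control), Fasl (962 ± 105, 377 ± 59.1 and 127 ± 15.2) and Lrrc32. Outside both controls in the same direction lay 98 genes. Of these, 66 were higher in ThpokAD than in either control, including Ccl4 and Prdm1, and 32 lower, including Il7r and Satb1. Both comparisons share the ThpokAD libraries. The correlation of their fold changes was 0.3535 against 0.5006 in the simulations, and the covariance 0.4998 against 0.2925. Again the correlation does not decide, for the same reason. The count of genes shared in the same direction (292) was 146, 129 and 164 without CD4 control replicates 1, 2 and 3 and 143, 194 and 150 without ThpokAD replicates 1, 2 and 3. That of opposite calls was 7, 5 and 5 without CD4 control replicates 1, 2 and 3 and 6 and 7 without ThpokAD replicates 1 and 3. That of genes outside both controls was 46, 42 and 43 and 29, 56 and 48 without the same CD4 control and ThpokAD replicates.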

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

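Tests with bias-adjusted deviances, with libraries thinned to equal depth, with camera on edgeR's count object and of the helper list without Zbtb7b and Tnfrsf4 were chosen only after the result was seen; the others were planned. No call turned its direction in any setting, and DESeq2's Wald test called 431 of the 431, 1836 of the 1839 and 1026 of the 1030 genes in the same direction. With that test 856 genes were higher and 613 lower in CD4 ThpokAD against CD4 control, 1457 and 1781 in CD8 control against CD4 control and 1530 and 856 in CD4 ThpokAD against CD8 control, with 846 shared in the same direction, 35 in opposite directions and 384 outside both controls. With only the 6 libraries compared, 246 were lower in ThpokAD against CD4 control. With the replicate number as a block, 86 were lower there and 183 lower against CD8 control, and 58 lay outside both controls. Limma-trend gave 478 higher and 277 lower in ThpokAD against CD4 control, 446 shared and 204 outside; bias-adjusted deviances gave 225 lower there, 1108 higher and 530 lower against CD8 control and 184 outside. At least a log2 fold change of 1 was reached by 84 lower genes in ThpokAD against CD4 control, 513 higher in CD8 control, 174 lower in ThpokAD against CD8 control, 190 shared and 6 opposite. Apart from fewer genes by construction at that size, the cause was not tested. Leaving out 1 library, higher and lower genes ranged from 131 to 281 and 50 to 196 in ThpokAD against CD4 control, 421 to 707 and 637 to 960 in CD8 control against CD4 control, and 438 to 586 and 143 to 222 in ThpokAD against CD8 control. Shared genes ranged from 129 to 293, opposite ones from 5 to 15 and those outside from 29 to 82. Of the 32 lists, 16, 23 and 18 passed camera in the 3 comparisons, 13 to 18, 21 to 23 and 17 to 19 without 1 library, and 8, 4 and 11 with an estimated correlation; fry in either direction passed 25 in ThpokAD against CD4 control. Camera on the count object added inhibitory receptors (adjusted p = 0.0213) and lost immediate early (0.158) and myeloid genes (0.0818) in ThpokAD against CD4 control, added chemokine receptors (0.0204) and lost dendritic (0.108) and ribosomal genes (0.059) in CD8 control against CD4 control, and lost cholesterol synthesis (0.0535) in ThpokAD against CD8 control. DESeq2's Wald test newly called 10 named genes, counted per comparison. Cd4, in ThpokAD against CD4 control, had an adjusted p of 0.00406 to 0.459 over all settings. Replicate numbers did not pair the libraries: across genes, correlations of same-numbered libraries were -0.045 to 0.062. In simulated data 18% of 2-fold changes were called, so small changes were mostly out of reach at 3 libraries per group.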

Other observations

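All tests of explanations in this part were chosen only after the result was seen. The glycolysis and fatty acid oxidation lists passed camera in no comparison of the main fit. Fry in either direction, which also takes in members that moved opposite ways, passed glycolysis in all 3 comparisons. Its adjusted p was 1.57e-07 for ThpokAD and 3.26e-07 for CD8 control, each against CD4 control, and 8.22e-06 for ThpokAD against CD8 control. At most 1 of its 21 members was called in either direction in any comparison. Fatty acid oxidation passed as higher in directional fry against CD4 control (adjusted p = 0.0104 for ThpokAD and 0.00442 for CD8 control) and in camera without the low-count filter for CD8 control (0.033). Among single metabolic genes, the glucose transporter gene Slc2a3 was at 342 ± 29.1 CPM in CD4 ThpokAD and 234 ± 36.1 in CD8 control against 83.7 ± 9.54 in CD4 control. Insig1, a sterol sensor, was 5.80-fold lower in CD8 control than in CD4 control.

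The interferon stimulated list passed camera in no comparison either, and the calls of the MHC class II and dendritic cell list against CD8 control were lost with an estimated correlation (adjusted p = 0.258 for CD4 control and 0.152 for ThpokAD). H2-Aa and H2-Ab1, chains of MHC class II, were at 167 ± 64.0 and 309 ± 115 CPM in CD4 ThpokAD, 148 ± 60.5 and 244 ± 122 in CD4 control and 32.9 ± 5.595 and 56.2 ± 7.30 in CD8 control. Whether these transcripts, and those of the myeloid and dendritic cell lists, came from other cells in the sorts was not tested. The interferon stimulated list did pass fry in either direction in all 3 comparisons. Its adjusted p was 6.68e-09 for ThpokAD and 3.75e-08 for CD8 control, each against CD4 control, and 8.94e-09 for ThpokAD against CD8 control. Among single interferon stimulated genes, Usp18, which dampens interferon signalling, was 2.50-fold higher in CD8 control than in CD4 control and 2.72-fold lower in ThpokAD than in CD8 control, while the interferon regulator Irf7 was 1.71-fold lower and 2.99-fold higher in the same comparisons.

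The 194 genes higher in both CD4 ThpokAD and CD8 control could reflect CD8 T cells in the ThpokAD sorts, or NK cells. Carried-over CD8 cells would raise each gene by the share that Cd8b1 shows, at most 2.198% of the CD8-CD4 difference. The genes reached a median of 99.8% (quartiles 67.37 and 133.6), which argues against this source for the set. Of them, 193 exceeded the highest share of Cd8b1. The genes were picked for being called higher in ThpokAD, which favours large shares, so that count alone does not decide on carried-over cells. For Cd8b1 itself, which reached 1.62% (SD 0.629, 0.949 to 2.198 by library), such cells and a rise within CD4 cells cannot be told apart. Cd8a reached 5.72% (SD 1.87, 3.82 to 7.56 by library), above the highest share of Cd8b1, which argues against such cells as the whole source of its rise. Against NK cells, the NK genes Tyrobp, Fcer1g and Ncr1 rose by 22.4 ± 13.6 CPM, 0.97% of the 2309 ± 193 CPM of Gzma, Gzmb and Prf1, and Klra8 had no count in ThpokAD. The NK marker list itself passed as higher, with Gzma, Klra1, Klra4 and Klrb1c called, all 4 of them also higher in CD8 control. A change of the CD4 cells of the ThpokAD mice may remain as a hypothesis found on these data. RNA of whole sorts does not tell a change within these cells from a change in their mix, and neither was tested.

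Most immediate early genes were lower in CD8 control than in either CD4 group. A heat-shock type response to handling that moved all members alike would lower the 6 heat shock members as much as the others. Their median log2 difference between CD8 and CD4 control was -0.35 (SD 1.02, 1 called lower, Hspa1a) against -3.35 for the 23 immediate early members. That argues against this form of response only. Of those 23, 21 were lower in CD8 control and 2 were called between the CD4 groups, which could follow from TCR engagement by the class II tetramer stain. The lineage, the viral peptide, the tetramer class and the sort go together in this design. TCR engagement by the stain, a handling response of immediate early genes alone and a lineage difference therefore cannot be told apart. The last 2 were not tested.

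Adamts14 and Pald1 (chosen after their values were seen for CD4 ThpokAD) lie on either side of Prf1 on chromosome 10, at 24394 and 14975 bp, and rose with it in ThpokAD and CD8 control, while the flanking Sgpl1 and Eif4ebp2 were not called. Read-through from Prf1 does not reach Adamts14, since that gene lies 24394 bp before the start of Prf1, which argues against this source for it. For Pald1, read-through in a fixed ratio would give 85.7 counts in CD4 control against 0 observed, but the gene was picked for such values and this cannot be told apart. Chance placement was tested on the 279 genes with a position among the 285 called higher in CD4 ThpokAD against CD4 control. Among them 31 neighbouring pairs lay within 100 kb, against a mean of 10.98 and at most 24 in 10000 random draws. With pairs that share the first 3 letters of the symbol left out, a rough mark of gene families, 20 pairs remained, against a mean of 9.97, and 23 draws held at least as many. Without the pairs of Adamts14 and Pald1 18 remained, and 122 draws held at least as many. These counts are over all genes called higher there and do not decide for Adamts14 and Pald1, for which chance placement cannot be told apart. A shared regional activation, untested, may be a candidate explanation.

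Other splits of the 6 libraries of each comparison into groups of 3 were counted. The 10 splits are too few for a share under 0.05. Each split other than the real one put libraries of both groups together. Differences between the groups then widened the spread within them, so few calls would follow from that alone. These counts therefore decide nothing. In CD4 ThpokAD against CD4 control 1 split, the real one, gave 431 genes and the highest other 0; in CD8 control against CD4 control 1 gave 1839 and the highest other 0; in CD4 ThpokAD against CD8 control 1 gave 1030 and the highest other 0.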
